A study of Mus musculus with 2 samples.

How the data were processed

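Monomethylation of histone H3 at lysine 4 (H3K4me1) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos at embryonic day 15.5. The labels give 1 group with 2 biological replicates. Replicate 1 was a pool of hearts from 78 embryos and replicate 2 a pool from 62 embryos, both of strain B6NCrl, a C57BL/6N substrain, with males and females mixed. Per the labels, the library size range was 300 to 500 in both. With a single group and no other tissue, stage or control sample, no test between conditions was possible.

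The deposited data are 4 lists of peaks in the narrowPeak format on the mm10 assembly. Per the labels' accompanying descriptions, the authors called peaks on each replicate alone, called peaks again on both replicates pooled, and derived a list of replicated peaks from the pooled list and both replicates' lists. Replicate 1's list was made from its alignments and 2 further inputs, and replicate 2's from its alignments and 1 further input, whose content is not stated. The aligner, the peak caller and its threshold are not given in the sources used here. The deposited signal value of a peak is its enrichment as the authors' caller wrote it, on a scale not given in the sources used here, and it served to rank, filter and describe peaks within a list and to correlate both replicates across shared peaks. The deposited −log10 p-value and −log10 q-value of each peak are the authors' as well, and the lowest −log10 p-value was 2.01 in replicate 1, 2.00 in replicate 2 and 2.03 among replicated peaks. The other deposited columns are the authors' peak starts, ends and summit offsets in bases. The lists hold no read counts, so sequencing depth is unknown, and differences in the number of peaks between replicates cannot be scaled to depth. Intervals given for shares of peaks are 95% Wilson intervals, and those and the intervals of odds ratios cover counting error only.

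Peaks on chromosomes 1 to 19 and X were used. This left out 2 peaks of replicate 1 and 3 pooled peaks on other contigs. Gene positions came from GENCODE mouse release M21 and sequence from the GRCm38 genome, which has the coordinates of mm10, and 0 peaks of any list reached past a chromosome end. All coordinates are 1-based on mm10. The measure per gene was the percent of the window from 50 kb upstream to 50 kb downstream of the most 5′ annotated start that replicated peaks covered, for 21728 protein-coding genes. Each replicate's own peaks gave the same measure, reported as mean and SD over both. The replicated list draws on both replicates, so it has no SD of its own. Its value can lie above the mean of the replicates, and the cause was not tested. Its peaks were called on pooled data, are wider at the median, and include 28514 with a base in replicate 1's peaks only.

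The 17 gene lists, the windows, the tests, the rule for named genes and all alternatives not listed as later additions were set before the data were examined. Named are the 5 genes with the highest coverage and the single lowest in each of 3 heart lists, the 2 highest of every other list, the genes at the 10 broadest domains (replicated peaks joined over gaps of up to 1 kb) and the genes at the 10 replicated peaks with the highest signal. All 391 list entries matched a gene. A list's median coverage was set against 10000 random lists of the same size, matched in 5 bins of gene length and 4 bins of the number of neighbouring gene starts, with a two-sided permutation p (2 times the smaller of the shares of random lists at or above and at or below the list, with the list itself counted among them) and Benjamini-Hochberg adjustment over the 17 lists. The pooled heart lists were set against 6 pooled lists of other tissues by a two-sided permutation test with 100000 resamples. Genes are not replicates, so these p-values describe these libraries and not the variation between hearts. A simpler form of the list test was tried on simulated data made from the real coverage of 21728 genes. It used fewer random lists, drawn without matching, and a p without adjustment over lists. It called 2% of 50 lists of 30 genes left as they were, 20% of lists raised 1.5-fold, 72% of lists raised 2-fold and 90% of lists raised 3-fold. These shares do not give the error or power of the matched and adjusted test.

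A peak counted as shared when peaks of the other replicate covered at least 50% of it, and chance sharing came from 100 circular shifts of the other replicate's peaks along each chromosome. Bases were classed as promoter-proximal (within 1 kb of a protein-coding transcript start), exonic, intronic or intergenic, in that order of precedence. Consensus sequences of 14 transcription factor families were counted on either strand in the central 500 bp of replicated peaks. The background was 1 window per peak outside all pooled peaks, matched on GC content. Fisher's exact test was used, with Benjamini-Hochberg adjustment over the 14. Windows are not replicates and neighbouring peaks can lie close together, so these p-values describe these libraries and not the variation between hearts. Alternatives were narrower and wider windows, gene bodies, stricter signal thresholds, the pooled list, each replicate left out, peak numbers in place of coverage, means in place of medians, random lists without matching, other overlap minimums, other promoter distances and other motif windows and backgrounds. Matching of random lists on GC content and repeat share, keeping 1 list member per 200 kb and matching of motif windows on repeat share were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.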

Results

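H3K4me1, a histone modification found at enhancers and beside active gene starts, was mapped in 2 pools of mouse hearts at embryonic day 15.5. The authors' lists held 225418 peaks in replicate 1 and 172282 in replicate 2 on chromosomes 1 to 19 and X, and 154981 replicated peaks. Replicate 1's peaks covered 119 Mb (4.65% of the called bases of the genome), replicate 2's 83.2 Mb (3.25%) and the replicated peaks 115 Mb (4.50%). The median peak width was 347 bp in replicate 1, 331 bp in replicate 2 and 525 bp among replicated peaks.

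The first question was around which genes the mark lay. Genes that build and control the heart muscle stood in the most broadly marked surroundings of the 17 lists examined. Genes of the cardiomyocyte contractile apparatus had a median of 22.1% of their 100 kb window covered by replicated peaks, genes of cardiac transcription factors 17.9%, and genes of conduction and calcium handling 16.6%. The median over all 21728 protein-coding genes was 5.57%. In the replicates' own lists the 3 medians were 18.7% ± 6.06, 15.2% ± 5.85 and 14.8% ± 5.53 (SD, n = 2), and in each replicate they were the 3 highest of the 17.

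Of the 30 contractile genes, 27 lay above the median of all genes and 17 in the top 10%. The highest was Tnni1, slow troponin I, with 49.0% of its window covered (replicates 44.2% ± 6.16, SD, n = 2) by 36 replicated peaks. Its gene lies at chromosome 1, 135779434 to 135810989, and Tnnt2, cardiac troponin T, starts downstream at 135836354 with 43.8% of its window covered (39.3% ± 7.21, n = 2). Tcap, the titin cap protein, had 48.4% (43.7% ± 6.87), Ldb3, a Z-disc protein, 46.0% (37.8% ± 9.16) and Tnnc1, cardiac troponin C, 43.6% (37.9% ± 8.26). The lowest was Xirp2, an actin-binding protein of the intercalated disc, with 0 replicated peaks in its window and 0.0960% ± 0.136 covered in the replicates. Its annotated gene (chromosome 2, 67446002 to 67526614) runs past the downstream end of the window, so a part of the gene is left out. The joined windows of Tnni1 and Tnnt2 span chromosome 1, 135729434 to 135886354, and reach into 6 protein-coding genes. There 46 replicated peaks covered 45.2% of the sequence. The last of them ended at 135863333, short of the gene Pkp1, which begins at 135871395. The peak with the highest signal in the Tnni1 window (135737664 to 135740418) lay 40.4 kb upstream of its start, inside the body of Csrp1.

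**Figure D1:**
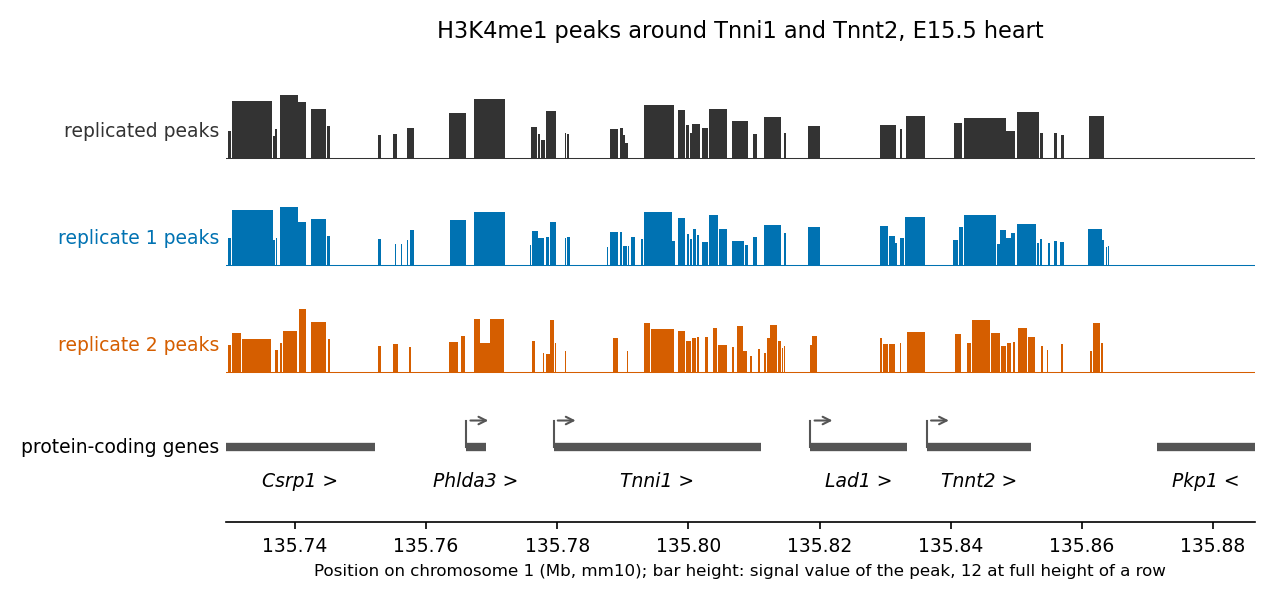
Replicated peaks and each replicate's own peaks across the joined windows of Tnni1 and Tnnt2 on chromosome 1 (horizontal axis in Mb, mm10). Bars are peaks, their height is the authors' signal value, and arrows mark gene starts; clusters of peaks recur in both replicates over the bodies of Csrp1, Tnni1 and Tnnt2, where replicated peaks covered 45.2% of the region.

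Of the 28 genes of cardiac transcription factors, 25 lay above the median of all genes and 12 in the top 10%. Tead1, a factor of the Hippo pathway, had 46.9% of its window covered (replicates 41.3% ± 6.19, SD, n = 2) and its strongest peak 17.1 kb downstream of the start, at chromosome 7, 112694057 to 112698748. Gata4, a zinc-finger regulator of heart formation, had 39.6% (34.0% ± 12.1), Prdm16 32.9% (27.2% ± 7.56), Hopx, a homeodomain-only protein, 30.9% (26.3% ± 8.65) and Myocd, the coactivator myocardin, 30.2% (25.9% ± 8.65). Smyd1, a muscle methyltransferase, was the lowest with 1.42% (1.15% ± 0.210). Its annotated gene (chromosome 6, 71213940 to 71322233) runs past the downstream end of the window, so this value leaves out a part of the gene. Of the 28 conduction and calcium genes, 20 lay above the median and 10 in the top 10%. Jph2, which ties the sarcoplasmic reticulum to the cell membrane, had 42.6% (38.0% ± 6.08), the potassium channel gene Kcnh2 41.9% (38.0% ± 6.37), the ryanodine receptor gene Ryr2 40.8% (34.5% ± 10.5), Kcnq1 39.9% (36.5% ± 7.45) and the calcium channel gene Cacna1h 38.6% (34.5% ± 6.62). The potassium channel gene Kcnd2 was the lowest with 0.560% (0.183% ± 0.0106). Its annotated gene (chromosome 6, 21215503 to 21729805) also runs past the downstream end of the window, so most of it is left out.

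Other lists stood lower (for each gene, coverage by replicated peaks, then mean ± SD in the replicates, n = 2). The 24 housekeeping genes had a median of 14.7%, led by the elongation factor gene Eef2 with 35.3% (30.7% ± 7.05) and the ribosomal stalk gene Rplp0 with 33.7% (31.7% ± 4.32). Smooth muscle and pericyte genes had a median of 11.4% (Des 42.6%, 38.2% ± 6.68 and Mcam 33.4%, 29.5% ± 6.93), genes of mitochondrial and fatty acid metabolism 10.6% (Idh2 38.5%, 33.4% ± 7.77 and Ppargc1a 26.5%, 21.1% ± 8.49), endothelial and endocardial genes 8.88% (Notch1 46.3%, 39.5% ± 4.16 and Eng 39.7%, 36.6% ± 6.40) and epicardial, fibroblast and valve genes 5.69% (Fbln2 23.7%, 20.3% ± 5.12 and Thy1 22.7%, 19.8% ± 3.02). Neural crest and glial genes had 8.90% (Dbh 33.5%, 29.9% ± 5.10 and Mpz 17.4%, 14.9% ± 4.12), white blood cell genes 7.17% (Fcer1g 26.3%, 21.9% ± 4.63 and Spi1 25.4%, 21.7% ± 6.20) and red blood cell genes 1.67% (Nfe2 with replicates at 21.8% ± 1.53 and Epor 14.5%, 12.9% ± 1.79), the lowest of the 17 lists. Lists of tissues outside the heart had medians of 12.5% for limb and posterior Hox genes (Hoxa9 18.3%, 15.5% ± 2.56 and Hoxa10 17.2%, 14.7% ± 2.91), 7.41% for lung and foregut epithelium (Sftpb 19.8%, 17.7% ± 4.56 and Cldn3 19.5%, 18.1% ± 3.47), 6.08% for neural transcription factors (Neurod2 31.4%, 28.3% ± 5.31 and Eomes 19.6%, 17.7% ± 3.24), 6.04% for skeletal muscle (Tnnt3 46.6%, 42.1% ± 4.59 and Tnni2 33.5%, 30.5% ± 3.99), 5.66% for liver (Apoa2 with replicates at 21.5% ± 4.84 and Hpd 16.7%, 15.9% in replicate 1 and 14.1% in replicate 2) and 4.72% for neuronal genes (Camk2a 32.1%, 28.2% ± 5.69 and Slc17a7 19.8%, 17.7% ± 3.60). Des, an intermediate filament gene, is also a member of the contractile list. Some of these members share sequence with heart genes or with each other. The strongest peak in the window of Neurod2, at chromosome 11, 98375953 to 98381056, lay 48.9 kb upstream of its start and within the window of Tcap. Spi1 had the same strongest peak as Mybpc3 of the contractile list (chromosome 2, 91068221 to 91069899). Fcer1g and Apoa2 also had the same strongest peak (chromosome 1, 171262010 to 171262856).

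Against random gene lists matched on gene length and neighbouring starts, 4 of the 17 lists were higher, none was lower, and 13 did not pass. The contractile list exceeded its random lists by 16.7 percentage points (random mean 5.44%), the cardiac transcription factor list by 14.4 (3.49%) and the conduction and calcium list by 11.8 (4.81%), each with an adjusted permutation p of 0.00113 (Benjamini-Hochberg). Before adjustment the permutation p of each was 0.0002, the smallest that 10000 random lists can give. With replicate 2's own peaks the 3 differences were 10.6, 8.77 and 7.55 points, with replicate 1's 17.3, 15.6 and 13.6, and with the 20000 replicated peaks of highest signal 3.09, 4.46 and 3.48. The housekeeping list exceeded its random lists by 7.88 points (6.86%, adjusted permutation p = 0.0127). Adjusted p for the other lists ran from 0.0564 for smooth muscle and pericyte genes to 0.850 for liver genes. The same 4 lists passed when random lists were also matched on GC content and repeat share (adjusted p 0.00170, 0.00170, 0.00227 and 0.0127), an alternative added after seeing the data. Their differences were smaller under this matching, 12.2 points for contractile, 10.9 for cardiac transcription factor, 9.59 for conduction and calcium and 5.86 for housekeeping genes. The list of neural transcription factors did not pass (adjusted permutation p = 0.0629). It did in 5 of 13 alternatives, among them windows of 25 kb on each side (8.35 points, adjusted permutation p = 0.00255), and its difference was 0.0472 points with random lists matched on GC content and repeat share.

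**Figure D2:**
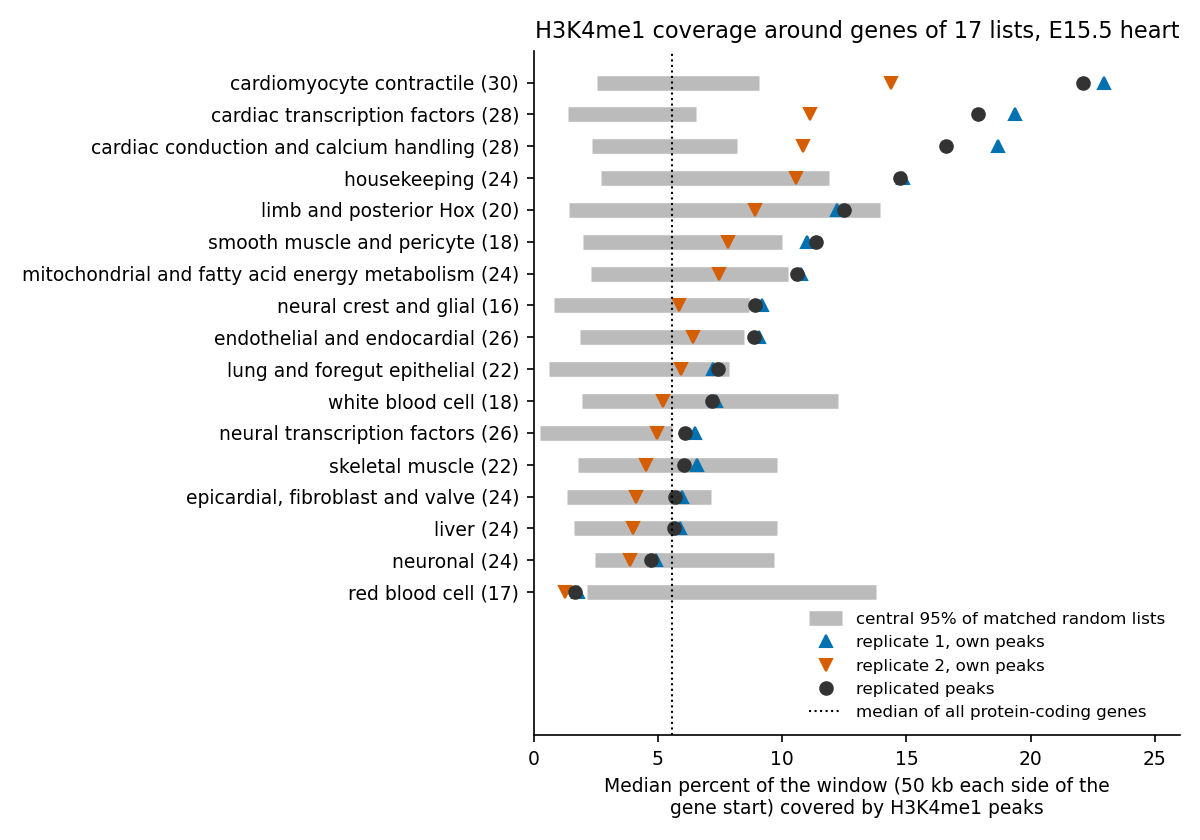
Median percent of the window around gene starts covered by H3K4me1 peaks for the 17 lists, with the number of genes in parentheses. Circles are replicated peaks, triangles each replicate's own peaks and grey bars the central 95% of matched random lists; the 3 heart lists, at 22.1%, 17.9% and 16.6%, lie above their bars in both replicates.

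Taken against the tissues outside the heart directly, heart genes had about 3 times the coverage. The 86 genes of the 3 heart lists had a median of 19.1% and the 138 genes of the neural, neuronal, liver, lung, limb and skeletal muscle lists 6.46%. The difference of 12.7 percentage points had a permutation p of 1e-05, the smallest that 100000 resamples can give. Genes were permuted singly, without matching and with neighbours kept, so this p counts members that share a window as separate. The limb and posterior Hox list, for example, has 9 of 20 members left at 1 per 200 kb. With replicate 2's own peaks it was 7.85 points and with replicate 1's 13.5, and with only the 20000 peaks of highest signal it was 1.79 points (permutation p = 0.00021).

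The widest domain of joined replicated peaks, 66.3 kb, lay at chromosome 4, 45457635 to 45523935, over exons and introns of Shb, an adaptor protein of receptor tyrosine kinases, and the replicates' own peaks covered 84.3% ± 6.63 of it (SD, n = 2). A domain of 61.3 kb over Sipa1l2 (chromosome 8, 125503581 to 125564835) followed, 78.4% ± 10.5 covered in the replicates. Tns1, which encodes the focal adhesion protein tensin, carried domains of 49.2 kb (chromosome 1, 73928137 to 73977298) and 45.2 kb (74011894 to 74057052). Myh9, non-muscle myosin heavy chain, carried 47.4 kb (chromosome 15, 77792963 to 77840378), and Smad6, an inhibitor of BMP signalling, 46.2 kb (chromosome 9, 63948277 to 63994492). The remaining domains among the 10 broadest lay over Pitpnm2 (47.3 kb), Map4k4 (46.8 kb), Vgll4, a cofactor of TEAD factors (44.9 kb), and Gse1 with the overlapping gene model Gm20388 (44.2 kb). Each of the 10 overlapped exons and introns, and none contained the most 5′ start of a protein-coding gene.

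The replicated peak with the highest signal value (−log10 p-value 64.2) covered the start of the fast skeletal troponin I gene Tnni2 and also overlapped Syt8 (chromosome 7, 142440321 to 142443368). The second lay in an intron of Ahdc1 (chromosome 4, 133019150 to 133028510) and the third, with a signal of 9.83, in intergenic sequence 34.5 kb from the start of Wasf2 (133094205 to 133095986). The others lay in Rara, the retinoic acid receptor alpha gene (9.75), 1.38 kb from the start of Junb, an AP-1 subunit (9.62), in Bcl9l (9.60), in the corepressor gene Ncor2 (9.55), 0.520 kb from the start of Ssbp3 (9.53), in the kinase gene Pim3 (9.43) and in an intron of Pcgf2 (9.43). Both replicates' own peaks covered at least 88.2% of each of these 10 peaks. These values are the authors' and rank peaks within their list.

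Relative to gene structure, the mark lay mostly in introns and between genes, and was most concentrated close to gene starts. Introns held 55.5% of replicated-peak bases (replicates 55.6% ± 0.214, SD, n = 2), intergenic sequence 26.2% (26.1% ± 1.12), promoter-proximal sequence 13.0% (12.9% ± 0.928) and exons 5.35% (5.42% ± 0.0264). Relative to the genome, promoter-proximal bases were 5.19-fold over their share, exonic 1.72-fold, intronic 1.56-fold and intergenic 0.444-fold. Each share lay outside the range of 100 circular shifts, which for promoter-proximal sequence was 2.35% to 3.08% and for intergenic sequence 54.6% to 59.6%. By distance, 16.2% of replicated peaks lay within 1 kb of a transcript start, 24.8% at 1 to 10 kb, 46.2% at 10 to 100 kb and 12.7% farther away.

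Around gene starts the mark formed shoulders on both sides of a dip. Replicated peaks lay over 16.7% of the starts of the 21728 genes (replicates 14.6% ± 3.39, SD, n = 2), 27.1% of positions 0.5 kb upstream (23.3% ± 4.54) and 35.8% of positions 1 kb downstream (31.4% ± 4.11). At 5 kb the shares were 6.33% upstream and 10.6% downstream. Of the 24 housekeeping genes, 4.17% had a peak at the start, at most 54.2% at any position upstream (900 bp) and at most 62.5% downstream (2200 bp). Of the 86 heart genes, 25.6% had a peak at the start, at most 45.3% upstream (1400 bp) and at most 44.2% downstream (4600 bp). The shapes for both sets are descriptions without a test.

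**Figure D3:**
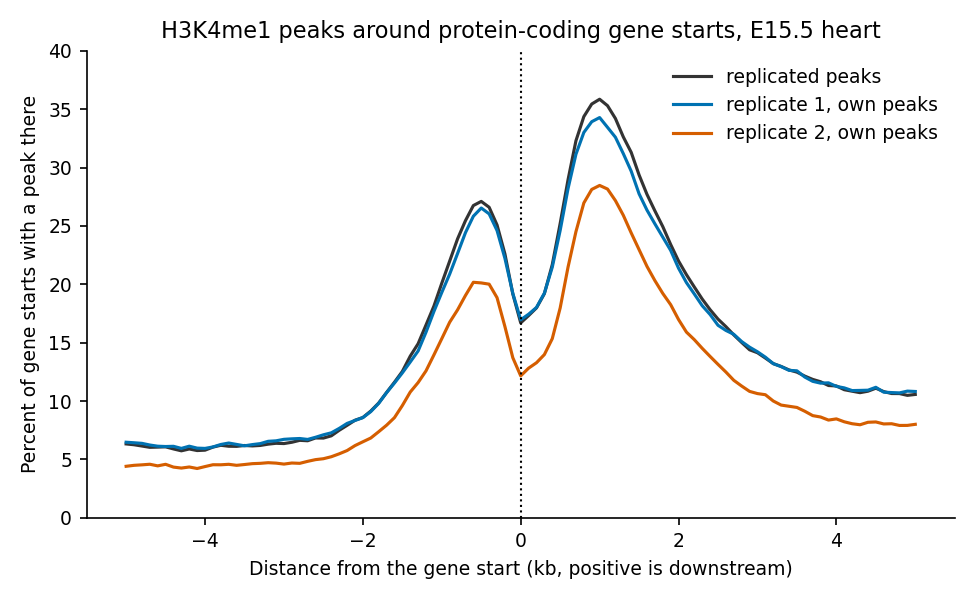
Percent of protein-coding gene starts with a peak at each distance (horizontal axis in kb, positive is downstream), for replicated peaks and each replicate's own peaks. All 3 lines dip at the start, where replicated peaks reach 16.7%, and peak at 1 kb downstream, where they reach 35.8%.

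The 500 bp at the midpoint of each peak were examined for consensus sequences of factors of the heart and of other tissues. In narrower peaks this window reached past the peak (lower quartile of width 337 bp), and in wider ones it left bases out. Shares of peaks given here are shares of these windows. Each name is that of the family a sequence was chosen for, and factor binding was not measured. The consensus of MEF2, a factor family of muscle differentiation (YTAWWWWTAR), was in 8.03% of replicated peaks and in 4.79% of GC-matched windows, an odds ratio of 1.74 (95% interval 1.69 to 1.79). The TEAD consensus was in 11.4% against 7.48% (odds ratio 1.60, 1.56 to 1.64), that of GATA factors in 41.4% against 33.9% (1.38, 1.36 to 1.40) and that of NKX2 factors in 13.5% against 10.8% (1.28, 1.25 to 1.31). The E-box of the TCF21 type was in 30.4% against 24.5% (1.34, 1.32 to 1.36) and the AP-1 consensus in 9.88% against 7.95% (1.27, 1.24 to 1.30). The neural bHLH E-box was less frequent in peaks, 11.4% against 12.1% (odds ratio 0.937, 0.917 to 0.958, Fisher's exact test, adjusted p = 1.25e-08). The SOX10 pair (odds ratio 1.58, adjusted p = 0.0415), ETS (1.25, adjusted p = 0.0191) and HNF4 (1.11, adjusted p = 0.0191) passed Fisher's exact test with few sites, between 63 and 1178 peaks each. TBX (0.975), SRF (1.03), REST (1.07) and HNF1 (1.00) did not pass, with adjusted p from 0.208 to 1.

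The background decided several of these values. Peaks had 48.6% GC, and against windows not matched on GC content (41.2% GC) the odds ratio was 0.659 for MEF2, 0.704 for GATA, 0.987 for NKX2 and 1.22 for the neural bHLH E-box, so the direction of all 4 held only at matched GC content. Peaks also held less repeat sequence than the matched windows (13.8% against 32.5%). With repeat share matched as well, added after seeing the data, the odds ratio was 1.99 for MEF2, 1.39 for TEAD, 1.34 for GATA, 1.19 for NKX2, 1.18 for the TCF21-type E-box, 1.10 for AP-1 and 0.928 for the neural bHLH E-box, all past Fisher's exact test, while it was 0.864 for ETS, 0.964 for HNF4 and 1.05 for the SOX10 pair, none of which passed. Under this matching TBX passed as less frequent in peaks (0.931, Fisher's exact test, adjusted p = 0.00285) and SRF as more frequent (1.10, Fisher's exact test, adjusted p = 5.88e-05), where neither passed with GC matching alone.

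**Figure D4:**
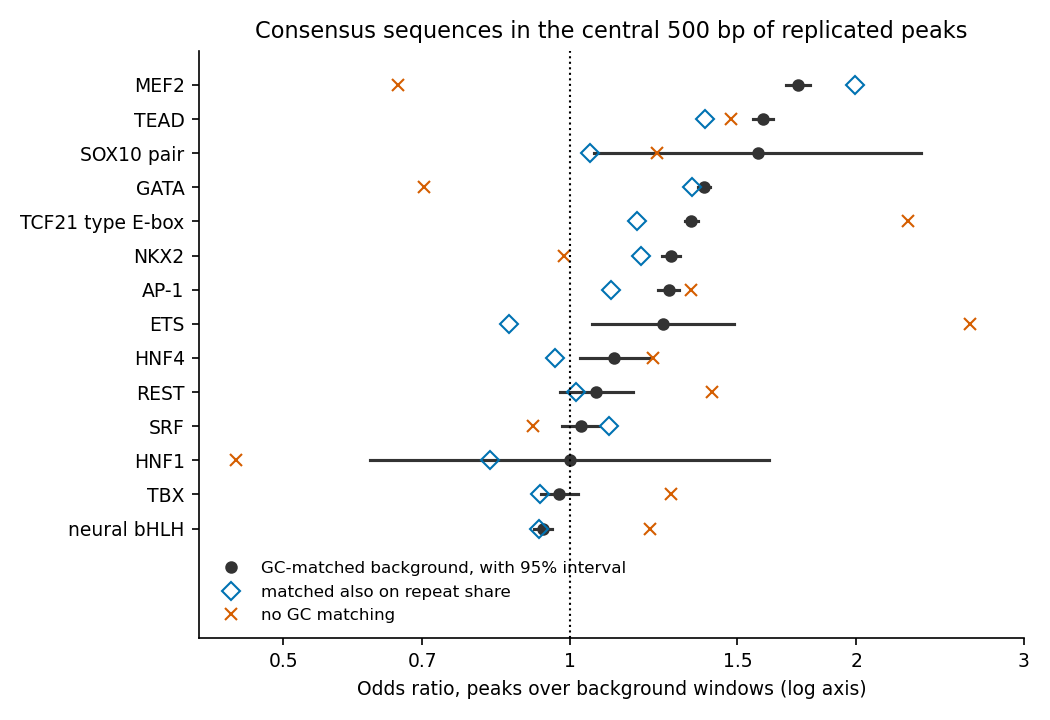
Odds ratio (log axis) of 14 consensus sequences in the central 500 bp of replicated peaks over background windows. Circles with 95% intervals use GC-matched windows, diamonds windows matched also on repeat share and crosses windows without matching; MEF2 lies at 1.74 with GC matching and at 0.659 without.

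The replicates were compared as the only comparison between samples in the design. Of replicate 1's peaks, 47.1% (95% Wilson interval 46.9% to 47.4%) had at least 50% of their length in peaks of replicate 2, and 79.0% (78.8% to 79.2%) of replicate 2's peaks did so in replicate 1. Circular shifts gave means of 3.28% and 4.83%. Sharing was highest for peaks of high signal, at 22.5% of replicate 1's peaks in the lowest signal decile and 93.4% in the highest. For replicate 2 it was 66.8% in the lowest decile, 62.8% in the next and 99.2% in the highest. Where 90% of a peak had to be covered the shares were 15.6% and 51.8%, and where 50% was required in both directions 36.2% and 47.4%. Across 117924 replicated peaks with a peak of each replicate, the log2 signal values of the replicates had a Spearman rho of 0.511 and a Pearson r of 0.541. This correlation is across peaks, which are not independent replicates.

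The replicated list held more than peaks found in both replicates. All 116991 pooled peaks that shared at least 50% of either peak's length with peaks of each replicate were in the list, and they made up 75.5% of it. Another 37057 replicated peaks (23.9%) had no base in a peak of one or both replicates, 28514 of them with a base in replicate 1's peaks only, 6250 in replicate 2's only and 2293 in neither. Of the pooled peaks, 62803 were outside the list, with a median signal of 2.30 against 3.05 inside it. All values given for replicated peaks include peaks without support in both replicates' own lists.

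Peak coverage differed between chromosomes, and the X chromosome stood far below the autosomes in both replicates. Replicated peaks covered 0.347% of the called bases of the X chromosome and 4.78% of those of the autosomes, with 6.62 and 64.2 peaks per Mb. In replicate 1's own list the coverage was 0.446% on the X chromosome and 4.94% on the autosomes, and in replicate 2's 0.196% and 3.46%. Among autosomes, replicated coverage ran from 3.33% on chromosome 3 to 7.62% on chromosome 11. The X-linked list members, looked up after seeing the data, had 0% of their windows covered for Gata1, a regulator of red blood cell formation, and for the myelin gene Plp1, 0.272% for Dcx, 0.537% for Alas2, 1.05% for Syn1, 1.17% for Apln, 1.39% for Hprt and 1.66% for Pgk1. Syp, a synaptic vesicle gene, had 6.03%, above the median of all genes, and autosomal members such as Rhag (0%) and Psmb2 (0.690%) were as low as the X-linked ones.

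**Figure D5:**
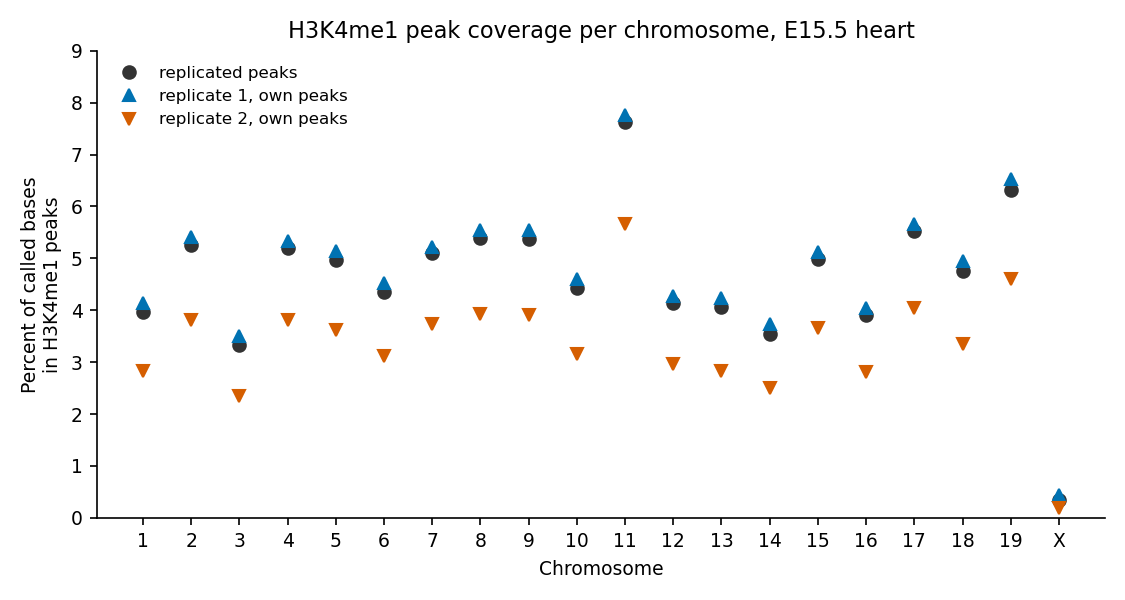
Percent of called bases in H3K4me1 peaks per chromosome (horizontal axis), for replicated peaks and each replicate's own peaks. The X chromosome lies at 0.347% for replicated peaks, against 3.33% for the lowest autosome.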

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

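Matching of random lists on GC content and repeat share, 1 member per 200 kb and motif windows matched on repeat share were chosen after seeing the data. No paired analysis was possible because there is 1 group. The calls of the 3 heart lists and the housekeeping list held in all 13 alternatives each (highest adjusted p 0.0034 and 0.0224), and the heart against other-tissue difference in all 10 (permutation p 1e-05 to 0.00021). Of 368 alternative values of the 46 named genes, 159 moved by less than the SD of the replicates. Causes of the changes listed here were not tested.

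Lists not called passed in some settings, given as percentage points over random lists. At 25 kb on each side these were energy metabolism 6.34, endothelial 5.54, red blood cell −6.50, skeletal muscle 6.11, neural transcription factors 8.35 and lung 7.87, and at 100 kb red blood cell −5.77 and lung 5.67. Over gene bodies they were energy metabolism 7.67, endothelial 7.33, epicardial 6.06, smooth muscle 7.62, red blood cell −7.03, neural transcription factors 14.9 and lung 6.39. With means they were energy metabolism 4.69 and smooth muscle 6.57, and with peak numbers smooth muscle 10.6 peaks. Above the median signal, neural transcription factors gave 4.35, and with the 20000 top peaks they gave 2.69 and lung 2.30. Leaving out a replicate gave 3.30 to 3.80 for neural transcription factors, which passed without replicate 1 only.

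Directions that turned all belonged to lists that did not pass. They were, without matching, epicardial −0.0404 and liver −0.139; with GC and repeat matching, epicardial −0.00358, white blood cell −2.88, skeletal muscle −2.68, liver −0.920, lung −0.587 and Hox −1.77; at 25 kb, white blood cell −2.44 and liver −3.42; at 100 kb, liver −1.37; over gene bodies, liver −3.70; with peak numbers, white blood cell −0.0485 and liver −2.10; with means, white blood cell −0.578 and liver −1.40; with the 20000 top peaks, neuronal 0.240; and with a replicate left out, neuronal −0.914 to 0.101, turned without replicate 1.

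Odds ratios of motifs without GC matching were 2.63 for ETS, 2.27 for the TCF21-type E-box, 1.48 for TEAD, 1.34 for AP-1 and 1.22 for HNF4. Also without GC matching, odds ratios were 0.659 for MEF2, 0.704 for GATA, 0.987 for NKX2, 1.28 for TBX, 0.916 for SRF, 0.446 for HNF1, 1.24 for the SOX10 pair, 1.41 for REST and 1.22 for the neural bHLH E-box. With repeat matching they were 0.931 for TBX, 1.10 for SRF, 0.864 for ETS, 0.964 for HNF4 and 1.05 for the SOX10 pair. In the central 200 bp they were 1.01 for TBX, 1.13 for ETS and 2.18 for the SOX10 pair, and in the central 1000 bp 0.982 for SRF and 1.06 for HNF4. Above the median signal they were 1.08 for SRF, 0.904 for ETS and 1.17 for the SOX10 pair. Over 1 kb from gene starts they were 1.04 for TBX, 1.17 for ETS, 1.10 for HNF4 and 0.952 for REST. In all 5 GC-matched alternatives the odds ratio stayed above 1 for MEF2, TEAD, GATA, NKX2, the TCF21-type E-box and AP-1.

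Shares of replicate 1's and replicate 2's peaks found in the other were 59.0% and 85.8% at 1 bp, 56.3% and 83.7% at 25%, 15.6% and 51.8% at 90%, 36.2% and 47.4% in both directions, 44.3% and 81.2% at a −log10 q-value of 2 or more, 50.1% and 62.8% for the 50000 top peaks, 44.9% and 74.0% above the median signal, and 45.5% and 80.6% for joined peaks. Above the median signal rho was 0.395 and r 0.423.

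Promoter-proximal enrichment was 4.50-fold within 2 kb and 5.78-fold above the median signal. Exonic enrichment was 1.44 within 2 kb, 1.95 within 500 bp and 1.79 above the median signal, intronic 1.46, 1.64 and 1.57, and intergenic 0.469 within 500 bp and 0.409 above the median signal. Leaving out a replicate gave 1.73 to 1.74 for exons and 1.56 to 1.57 for introns. Above the median signal the profile had 12.6% at the start, at most 18.7% upstream and 28.9% downstream, 4.52% at 5 kb upstream and 7.53% at 5 kb downstream, and leaving out a replicate gave, in the same order, 12.2% to 17.0%, 20.2% to 26.5%, 28.5% to 34.3%, 4.41% to 6.48% and 8.01% to 10.8%. Depth is unknown, so which weak peaks it leaves out cannot be stated.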

Other observations

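The tests in this part were chosen after their patterns had been seen, with each prediction set before the test's own result. The genes named in the next paragraph were picked after their values were seen.

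Among all 21728 protein-coding genes, the windows with the highest coverage were those of Col4a1 and Col4a2, neighbouring genes on chromosome 8 for the type IV collagen of basement membranes, with 63.8% each (replicates 56.0% ± 10.3, SD, n = 2). Igf2r, the receptor that clears the growth factor IGF2, had 63.2% (58.6% ± 5.23), Ifrd2 58.8%, Zmiz1 58.3% (54.9% ± 4.43) and Zfpm1, a partner of GATA factors, 56.5% (51.9% ± 4.18). Domains of joined peaks of at least 10 kb numbered 847. They overlapped 26 of the 86 heart genes (30.2%), among them Gata4, Gata6, Hcn4, Myh7, Ryr2, Tnnt2 and Tead1, where other genes of the same length gave 4.41%, and 679 of the other 21642 protein-coding genes (3.14%). No test was made of this difference. At the other end, 0% of the window of the adult beta-globin gene Hbb-bt and 0.310% of that of the embryonic gene Hbb-y were covered. Of all protein-coding genes, 17.2% had no coverage. The alpha-globin gene Hba-a1 had 6.99%, above the median of all genes (5.57%).

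The higher coverage at the 3 heart lists was tested against GC content, repeats and gene density, and against list members that share a window. With random lists matched also on GC content and repeat share, the highest adjusted p of the 3 lists was 0.00227, and with 1 member kept per 200 kb it was 0.00113, so neither accounts for the pattern as a whole. The differences of 16.7, 14.4 and 11.8 points fell to 12.2, 10.9 and 9.59 with GC and repeat matching, so sequence content may account for a part. That the mark follows the genes in use in heart cells is a hypothesis and was not tested, because the design has no other tissue or stage. Not all values point its way: the list of epicardial, fibroblast and valve genes had 5.69% against 5.57% for all genes, the endothelial list had an adjusted p of 0.692 with GC and repeat matching, and the cardiac actin gene Actc1 had 4.32%.

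The few peaks on the X chromosome were tested against copy number and against sequence content. If 3 X copies per 4 of an autosome lowered every −log10 p-value to 0.75 of its size, 96.7% of autosomal peaks in replicate 2 and 97.9% in replicate 1 would still pass the lowest value in their list, and 76.9% and 79.6% at a factor of 0.5, whereas peaks per base on the X chromosome were 8.74% and 13.6% of those on autosomes. This argues against copy number as the whole cause, under the assumption that the value falls in proportion to copies. Windows of 100 kb matched on GC content, repeats and gene starts gave a higher X to autosome coverage ratio. It rose from 0.0918 to 0.318 in replicate 1 and from 0.0575 to 0.217 in replicate 2. These properties may account for a part, and matching on them left a gap in both replicates. Other sequence properties, and sequence content together with other causes, were not tested. Full silencing of an X in female cells would leave 1 active X per 2 copies of an autosome in both sexes, the factor of 0.5. At that factor 76.9% and 79.6% were left, against 8.74% and 13.6% seen. Whether the −log10 p-value falls in proportion to copies was not tested, and it may fall faster. The median autosomal signal was 2.95 in replicate 1 and 3.14 in replicate 2, and the lowest signal 1.45 and 1.60. A factor of 0.5 on the signal would bring a median peak near that lowest value. These values therefore cannot decide about silencing. Silencing remains open, and mappability and the caller's treatment of the X chromosome remain open and untested.

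Replicate 2 covered less than replicate 1 in all 17 lists, and more so around heart genes than elsewhere, where the ratio of mean coverage was 0.680 (14.5% against 21.3%) and 0.734 at other genes. Among lists of genes with the same mean coverage over both replicates, the central 95% of ratios was 0.765 to 0.797. This argues against a loss set by breadth of coverage alone. With 172282 top-ranked peaks taken from each replicate the ratio was 0.743 against 0.823 to 0.859, which argues against peak number alone, and with lists matched also on GC content, repeats and gene starts it was 0.680 against a mean of 0.769. No list was matched on peak signal, so these values cannot tell whether heart genes lost more through weaker peaks. Replicate 1's peaks were shared least at low signal (22.5% in the lowest decile, 93.4% in the highest). With only the 20000 replicated peaks of highest signal, median coverage fell from 19.1% to 4.21% at heart genes. At genes of the other tissues it fell from 6.46% to 2.42%. By list, the ratio was 0.664 for cardiac transcription factors, 0.677 for conduction and calcium handling and 0.694 for contractile genes. The lists of mitochondrial and fatty acid metabolism (0.666), liver (0.678) and limb and posterior Hox genes (0.692) had ratios as low as the heart lists, and skeletal muscle (0.773) the highest. A lower share of heart muscle cells in the pool of replicate 2 may account for the heart lists and was not tested. The liver and Hox ratios cannot decide about it. These lists had lower mean coverage (6.70% and 12.3% in replicate 1) and were not set against lists of the same coverage. A greater loss of weak peaks in replicate 2 and differences in the immunoprecipitation or in the inputs used for calling remain open.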
